A study of Mus musculus with 12 samples.

How the data were processed

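CUT&RUN was performed on GFP-sorted CaMK2a-lineage nuclei of mouse CA1 with a c-Fos or an IgG antibody, after kainic acid or PBS, with 3 replicates in each of 4 groups. Groups were taken from the sample labels. The series description calls the replicates biological, without saying how many animals each one held. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2 2.2.9, bedtools 2.27.1 and SEACR 1.1 were used with the genome builds mm10 and sacCer3. The role, order and settings of these tools are not given in the sources used here. The deposited file is a peak list with 3 columns, chromosome, start and end, and has neither header nor score. Its name describes the peaks as replicated and as c-Fos against IgG after kainic acid. It is attached to 1 sample of that group and was treated as a list of the whole group. How peaks were combined over replicates, and the threshold used, are not given in the sources used here, so peaks weaker than that unknown threshold are missing from every count. Read depth per library is unknown, so no interval below covers sequencing error or variation between replicates; exact binomial (Clopper-Pearson) and Poisson intervals at 95% cover counting error over peaks or genes only.

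Of the 3295 peaks, the 3294 on 20 chromosomes (19 autosomes and X) were used for the descriptions and tests; 1 peak lay on an unplaced sequence. Positions are given 1-based on mm10. Genes came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 represents, which listed 49997 genes with chromosome, start and end. It carries no strand, exons or sequence. On these chromosomes, 340 genes (108 protein-coding) starting below 3000000 were left out, since their coordinates appeared to refer to unplaced scaffolds: the highest end among them was 2838604 and the lowest start kept was 3000138. This left 21523 protein-coding genes.

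Tests were fixed before the data were examined, and several had to be adapted. Because strand was missing, both ends of each protein-coding gene stood in for the transcript start, which mixes promoters with transcript ends. Features were reduced to inside or outside protein-coding genes. The planned tests of the AP-1 motif (its share, centring and share by location), of the panel of other motifs and of repeats need a genome sequence and were not run. A gene counted as having a peak when a peak midpoint lay within 100 kb of either of its ends.

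Peak positions were compared with 1000 random placements of the same widths on the same chromosomes. Placements ran over the span of genes and peaks on each chromosome. Assembly gaps inside that span could not be excluded, contrary to the plan. Clustering was the share of peaks with another midpoint within 12.5 kb. Peaks per chromosome were compared with 10000 multinomial draws by span. The 16 gene lists (391 entries, 377 distinct genes, all matched to the gene table) were written before the data were examined. Each was compared with 10000 random lists of the same size drawn from the same quintiles of gene length and of gene number within 100 kb. Pairs of lists were compared with a two-sided Fisher's exact test. Monte Carlo p-values are two-sided, and the smallest possible value is 0.0002 with 10000 draws and 0.002 with 1000. Benjamini-Hochberg adjustment ran over the 16 lists, the 20 chromosomes, the position measures or the pair of planned list comparisons, with a threshold of 0.05. Genes that share a peak are not independent, which matched random lists ignore; circular shifts of all peaks along their chromosomes (10000) were therefore added.

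Genes named in the report followed a rule set in advance. It took up to 12 members with the nearest peaks from each activity-induced list (with Fos, Fosb, Junb, Npas4, Arc, Bdnf and Scg2 always), up to 4 from each other list, the 10 genes with most peaks within 100 kb, and the nearest genes of the 10 widest peaks. Genes of the densest 1 Mb regions were named after their values were seen. Not every gene chosen by the rule is named, and some are not reported here.

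Alternatives were the wider peaks (1647), merging within 500 bp, other windows and distances, all gene types, local placements within 250 kb for gene ends and clustering, other links of peak to gene, and no matching. The link to the nearest gene only reached up to 1 Mb from a gene end, farther than the main 100 kb. Chosen after seeing the data were circular shifts, a link of the gene body with 100 kb around it, gene number as chromosome size, local placements for the distance and the share inside genes, and leaving out the X chromosome, peaks over 5 kb or the 3 densest regions. The list and placement tests were tested on simulated peaks. In 40 sets of 3294 randomly placed peaks, 26 of 640 list tests (4.06%) had an unadjusted p under 0.05, the gene-end test was positive in 2 sets and the clustering test in 0. With peaks planted at a random list of 39 genes, at gene ends and beside other peaks, each of these tests was positive in 40 of 40 sets. The randomly placed peaks lacked the clustering of the real list, so they do not show how the list test behaves with clustered peaks. Weaker planted effects were not simulated. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.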

Results

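Binding of c-Fos, an AP-1 transcription factor subunit that neurons make within minutes to hours of strong firing, was profiled in nuclei of CA1, a pyramidal cell field of the mouse hippocampus. Nuclei carried Sun1-GFP, a fluorescent nuclear envelope tag switched on by CaMK2a-Cre in excitatory neurons, and were sorted on that tag. Mice aged 3 to 4 weeks received kainic acid, a glutamate receptor agonist that drives seizure-like firing, or phosphate buffered saline (PBS), and tissue was taken 2 to 3 h later. CUT&RUN, in which an antibody directs a nuclease to cut out the bound DNA for sequencing, was run with a c-Fos antibody or with IgG as the negative control, on 50000 nuclei per reaction. The 12 samples formed 4 groups of 3 replicates. The values used here were the positions of 3295 peaks described as replicated in c-Fos against IgG after kainic acid. The list held no signal, score or value per library, so the read depth is unknown and no spread between replicates could be given. All p-values below concern the positions and widths of peaks within this 1 list, not variation between animals.

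The first question was which genes of CA1 neurons lay near c-Fos peaks after kainic acid. Genes known to be switched on by neuronal activity stood out. Of 39 activity-induced effector genes, which encode secreted, synaptic and signalling proteins, 22 (56.4%, exact 95% interval 39.6 to 72.2) had a peak within 100 kb of a gene end, against 8.37 in random gene lists matched on gene length and local gene density. Of 24 activity-induced transcription factor genes, 11 (45.8%, interval 25.6 to 67.2) had one, against 4.36. Among all 21523 protein-coding genes, 4563 (21.2%) had a peak at that distance.

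Scg2, which encodes the neuropeptide precursor secretogranin II, had 3 peaks. The nearest, on chromosome 1 from 79439240 to 79440824 (mm10), had its midpoint 6 bp beyond one end of the gene, and another lay 2.16 kb from the opposite end. Bdnf, encoding brain-derived neurotrophic factor, also had 3 peaks, all on the side of lower coordinates. The nearest, on chromosome 2 from 109673449 to 109675418, was centred 267 bp from the gene end, and the others lay 35.7 and 55.6 kb away. Arc, a regulator of glutamate receptor trafficking, had a peak of 3956 bp that spanned most of the gene on chromosome 15 (74669102 to 74673057) and 2 further peaks within 100 kb. Homer1, which encodes a postsynaptic scaffold protein, had a peak centred inside the gene, 260 bp from its end. The genes Trib1, Dusp1, Gadd45b, Rheb, Pim1 and Rgs2 had their nearest peak 270 to 614 bp from a gene end. Dusp1 encodes a phosphatase that switches off MAP kinases, and Rgs2 a brake on G protein signalling. Nptx2, encoding a secreted pentraxin that clusters AMPA receptors, and Ccn1 had theirs at 2.44 and 2.66 kb.

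Among the transcription factor genes, Klf4, Fosl2 and Maff had a peak 690, 707 and 810 bp from a gene end. Junb had 1 peak 7.08 kb away, on chromosome 8 from 84984720 to 84986927. Fos itself had 2 peaks, at 18.4 kb on one side and 9.58 kb on the other, and none inside the gene. Nr4a2 (14.9 kb), Jun (25.7 kb), Atf3 (40.8 kb), Ier5 (45.2 kb), Egr2 (47.0 kb) and Crem (97.8 kb) had their nearest peak farther out. Fosb and Npas4, both induced early by activity, had no peak within 100 kb, and their nearest peaks lay 406 and 820 kb away.

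Both activity-induced lists passed the threshold among the 16 lists tested (Monte Carlo test against 10000 matched lists, Benjamini-Hochberg adjusted p = 0.0032 for the effectors, n = 39 genes, and 0.0336 for the transcription factors, n = 24 genes). When the expectation came instead from shifting all peaks along their chromosomes, a choice made after the data were seen, the effectors kept an adjusted p of 0.0032. The transcription factors did not pass (2.16 times the expectation, adjusted p = 0.0976, n = 24 genes).

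**Figure D1:**
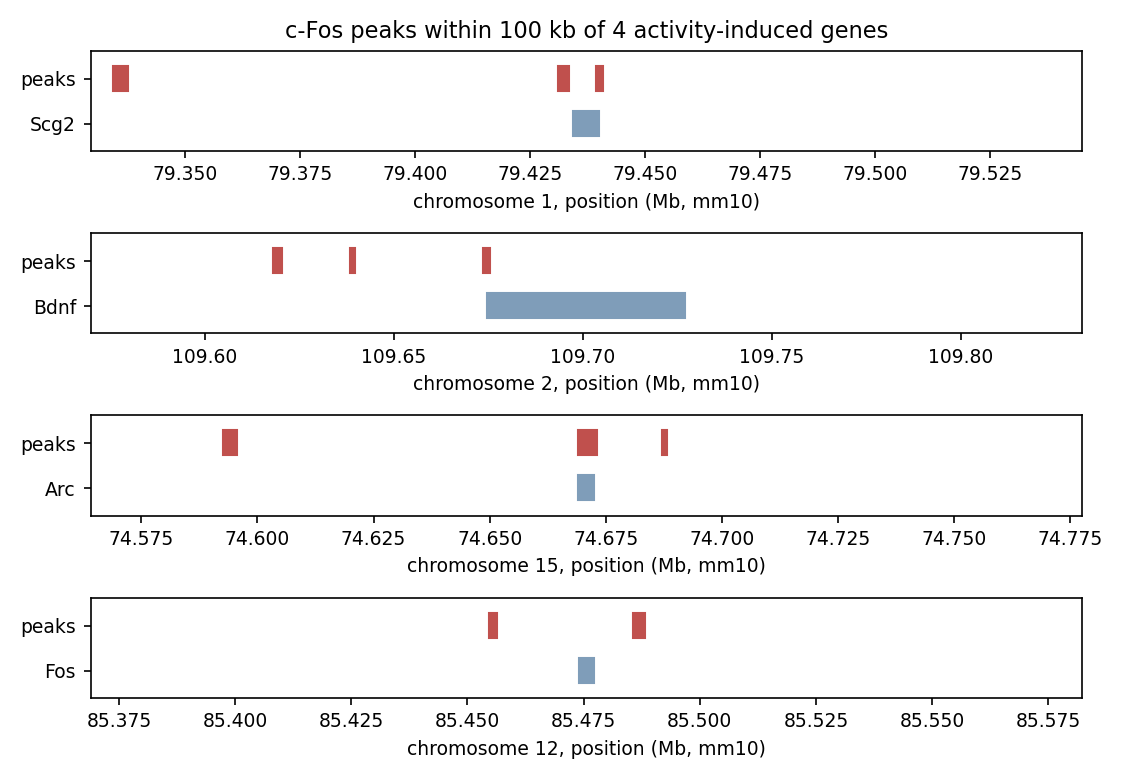
Positions of c-Fos peaks (upper boxes) and gene extents (lower boxes) around Scg2, Bdnf, Arc and Fos, with the mm10 coordinate in Mb on each horizontal axis. Scg2, Bdnf and Arc each have 3 peaks within 100 kb and Fos has 2.

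The next comparison set activity-induced genes against genes that mark cell types, to ask whether peaks favoured inducible genes over genes of the same or other cells. Activity-induced genes had a peak more often than markers of interneurons, astrocytes, oligodendrocytes, microglia and vascular cells as 1 set. The shares were 33 of 62 (53.2%) and 26 of 95 (27.4%), an odds ratio of 3.02 (interval 1.46 to 6.25, two-sided Fisher's exact test, adjusted p = 0.00273). A gene present on both sides was left out. Before that, interneuron markers alone had 11 of 26 (42.3%) and glial and vascular markers 15 of 70 (21.4%). Activity-induced genes were not compared with interneuron markers alone. With peaks counted in the gene body and 10 kb around it, the difference was 14.3 percentage points and did not pass (Fisher's exact test, adjusted p = 0.0838). Against pyramidal neuron markers, 10 of 24 of which (41.7%) had a peak, the difference was 10.7 percentage points and did not pass (33 of 63, exact p = 0.473, odds ratio interval 0.539 to 4.49). Pyramidal markers with the nearest peaks were Zbtb20, a transcription factor of CA1 identity (118 bp), Spink8 (3.39 kb), Neurod6 (5.34 kb) and Slc17a7, the vesicular glutamate transporter VGLUT1 (14.1 kb).

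None of the other 14 lists passed the test. Interneuron markers had 11 genes with a peak against 6.28 expected (adjusted p = 0.239, n = 26 genes). The closest were at Gad1 and Gad2, which encode the enzymes of GABA synthesis (590 bp and 2.35 kb), at Dlx2, a transcription factor of interneuron development (695 bp), and at Slc32a1, the vesicular GABA transporter (2.47 kb). With peaks counted only within 10 kb of a gene end, the interneuron list did pass, with 7 genes against 1.29 (adjusted p = 0.0064, n = 26 genes). At that distance, 21 of 149 developmental transcription factor genes outside the list, a set drawn up after the peaks were seen, also had a peak, against 5.40 expected. Of the astrocyte markers 4 of 18 had a peak (Sox9 at 1.09 kb and S100b at 1.73 kb were nearest), of the oligodendrocyte lineage markers 3 of 18 (Mbp, 47.8 kb), of the microglia markers 4 of 18 (Aif1, 5.80 kb) and of the vascular markers 4 of 16 (Rgs5, 19.8 kb). Each of these 4 lists had an adjusted p of 1. Markers of dentate gyrus and CA3, the neighbouring hippocampal fields, had 2 of 16, at Plekha2 (10.5 kb) and Rnf182 (13.6 kb), with an adjusted p of 0.608.

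Genes of synapses and secretion did not pass either under the main link, which misses peaks more than 100 kb from both ends of a long gene. Of the glutamatergic synapse genes, 13 had a peak against 8.30 expected (adjusted p = 0.239, n = 28 genes), with Lrrtm2, a postsynaptic adhesion protein, at 197 bp and Shank2, a scaffold protein, at 8.31 kb. Homer1, with a peak at 260 bp, is on this list and also among the effectors. The glutamatergic list passed when only the gene nearest to each peak was counted (16 genes against 6.29, adjusted p = 0.0016, n = 28 genes). Of the inhibitory synapse and GABA receptor genes, 11 had a peak against 7.43 (adjusted p = 0.354, n = 24 genes), with Gabra2, a GABA-A receptor subunit, at 17.1 kb. Of the neuropeptide and secretory granule genes, 11 had one against 6.26 (adjusted p = 0.239, n = 28 genes), and this list shares Scg2 and Bdnf with the effectors. Sst, encoding somatostatin, had its nearest peak at 4.35 kb and Chgb, encoding chromogranin B, at 39.3 kb. Voltage-gated ion channel genes had 7 (adjusted p = 0.769, n = 29 genes), with Cacna2d1 at 18.6 kb. The adjusted values were also above the threshold for AP-1 partners and cofactors (8 of 22, 0.608), with Mafk at 5.19 kb, for housekeeping genes (9 of 30, 0.327), with Ywhaz at 9.28 kb, and for genes of other organs (5 of 30, 1), with Gcg at 19.5 kb.

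**Figure D2:**
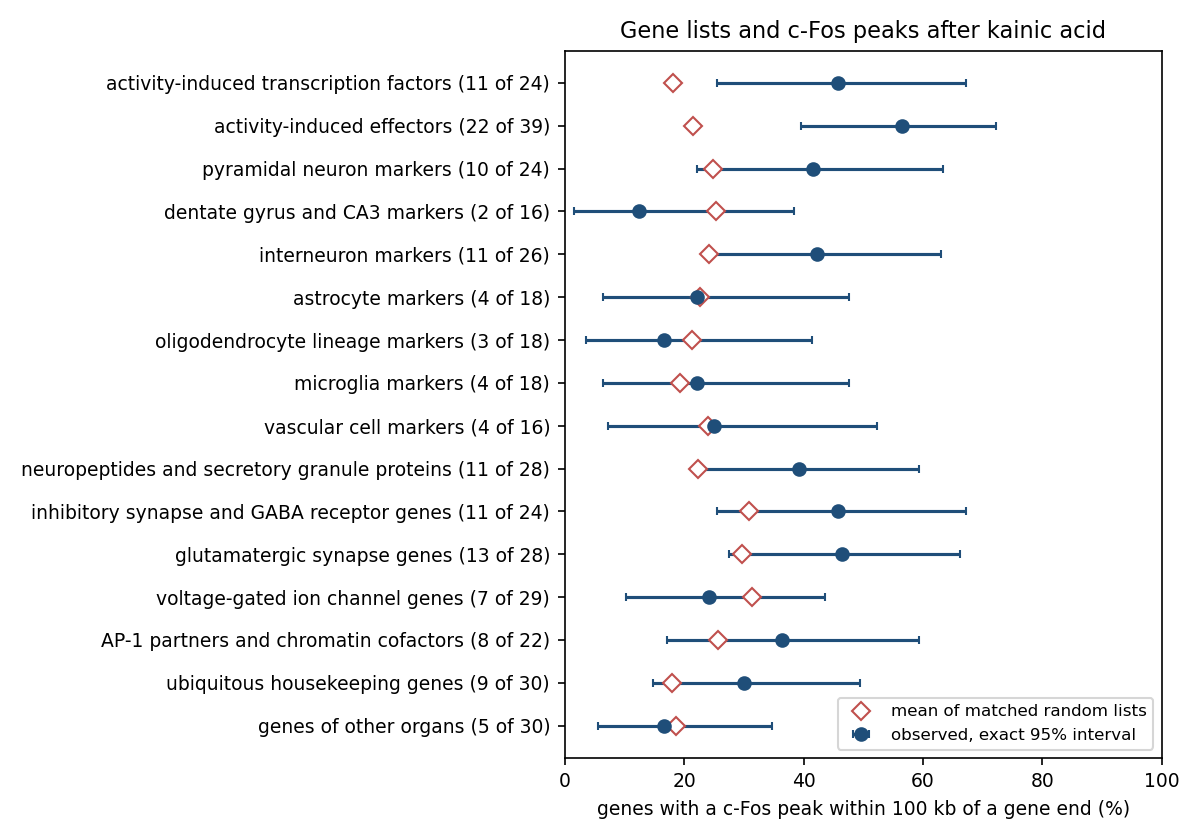
Share of genes with a c-Fos peak within 100 kb of a gene end (horizontal axis, %) for each of the 16 lists. Filled circles give the observed share with its exact 95% interval and open diamonds the mean of matched random lists; the effectors (56.4%) and the activity-induced transcription factors (45.8%) lie farthest above theirs.

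The position of peaks relative to genes was examined next. Peaks gathered directly at gene ends and inside genes, and thinned out between 1 and 10 kb. Of 3294 peaks on assembled chromosomes, 220 (6.68%, interval 5.85 to 7.59) had their midpoint within 1 kb of an end of a protein-coding gene, 2.17 times the 3.07% ± 0.30 (SD over 1000 random placements) of random positions. Inside protein-coding genes lay 1718 peaks (52.2%, interval 50.4 to 53.9), against 40.8% ± 0.86. With placements within 250 kb of each peak, chosen after the data were seen, the expected share inside genes rose to 48.1% (ratio 1.08). Between 1 and 10 kb from a gene end lay 480 peaks (14.6%), against 18.3%, and 1506 (45.7%) lay 10 to 100 kb away, against 42.9%. Beyond 100 kb were 1088 peaks (33.0%), against 35.7%. Each of these shares passed a two-sided Monte Carlo test (adjusted p of 0.0030 to 0.0048, of which the lower is the smallest that 1000 placements and this adjustment gave). The median distance to the nearest gene end, 49.7 kb, did not differ detectably from the 48.3 kb of random placements (p = 0.452, n = 3294 peaks). Strand was not used, so a gene end is either the start or the end of transcription.

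**Figure D3:**
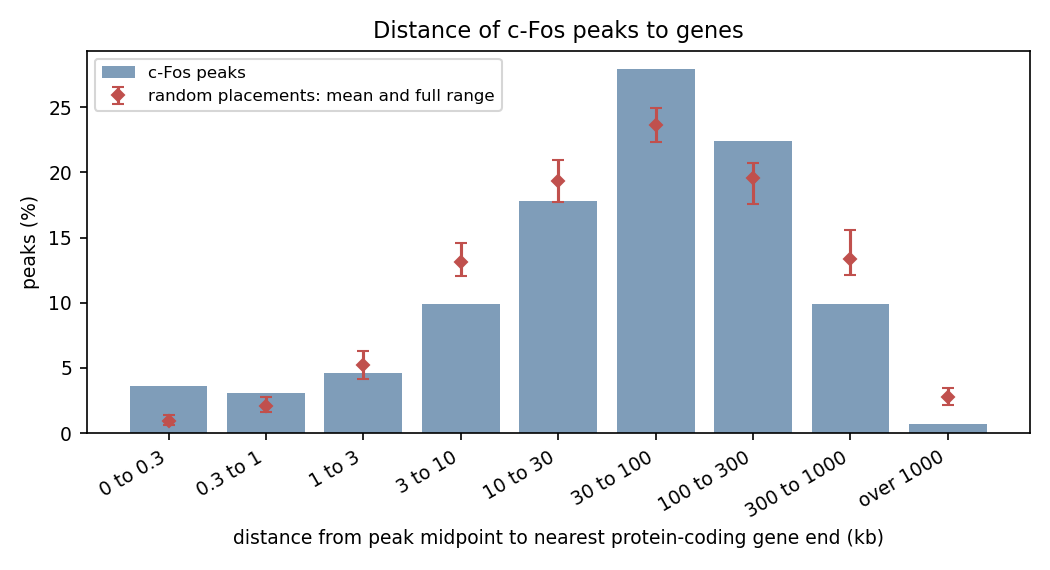
Share of c-Fos peaks (bars, %) by distance from the peak midpoint to the nearest protein-coding gene end in kb, with the mean and full range of 100 random placements (diamonds and whiskers). Bars exceed the placements up to 1 kb and between 30 and 300 kb, and lie below them from 3 to 10 kb and beyond 300 kb.

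Peaks also lay close to one another, and the 10 regions of 1 Mb with the most peaks differed in how many lay inside genes. In 1 Mb of chromosome 17, 28 peaks were found, 26 of them inside Dlgap1, which encodes a scaffold protein of the postsynaptic density. In 1 Mb of chromosome 10, 22 peaks included 20 inside Syt1, the calcium sensor of synaptic vesicle release. Magi2, a synaptic scaffold gene on chromosome 5, held 15 peaks, Celf2, an RNA-binding protein gene on chromosome 2, held 13, and Nell2 on chromosome 15 held 8. On chromosome 14, 13 peaks (64256063 to 65256063) included 9 inside Msra, 2 inside Ints9 and 1 inside Extl3. In 4 of the 10 regions at most 1 peak lay inside a protein-coding gene. A region of chromosome 10 from 97940559 to 98940559 had 21 peaks and none inside such a gene, and the same held for 16 peaks on chromosome 2 (107041318 to 108041318, with Fshb and Kcna4) and 14 on chromosome 13 (110627212 to 111627212, with Actbl2). On chromosome 3, 15 peaks (84933682 to 85933682) included 1 inside Fbxw7. These regions were found by their peak number, after the positions were seen, and were not tested against gene length. Over the whole list, 455 peaks (13.8%, interval 12.7 to 15.0) had another peak within the clustering distance set in advance, 4.11 times the 3.36% ± 0.46 of random placements (p = 0.002, the smallest 1000 placements can give, n = 3294 peaks). Against placements within 250 kb of each peak, which keep the regional density, the ratio fell to 1.81 (7.65% ± 0.61). Of 251 gaps between such neighbours, 49 (19.5%) were under 1 kb, and the median gap was 3221 bp. Whether some neighbours were parts of 1 broader enriched region was not decided. Clustering was not recomputed with peaks within 500 bp merged.

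By the number of peaks within 100 kb, Gm5136 on chromosome 10 came first with 13. It lies within the extent of Syt1, so these peaks belong to the group described there. It was followed by Nell2 with 8, Hivep2 and Ndst3 with 7 each, and Gatb, St6galnac5, Cflar and Myo16 with 6 each. A further 20 genes had 5 each, and Wdfy2 and Hlx had the nearest peaks among them. The median peak was 1341.5 bp wide (quartiles 1097 and 1698.75 bp), and widths ran from 299 to 18691 bp. Nearest genes of the widest peaks included Mid1 on the X chromosome (18.7 kb wide), Sim1 (13.7 kb), Sfi1 (12.7 kb), Gm45988 (11.9 kb), Galr1 (7.90 kb), Atxn1 (6.93 kb), Gm20767 (6.61 kb), Gm38821 (6.40 kb) and Slc24a2 (6.21 kb). Those near Sim1, Sfi1, Atxn1 and Slc24a2 overlapped the gene. Width was not used as a measure of binding strength. Peaks in repeats or in poorly mapped sequence were not filtered out here, so a wide peak need not be a broad binding site.

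Across chromosomes, the X chromosome stood apart with few peaks. It held 21 peaks, or 0.125 per Mb (exact Poisson interval 0.0776 to 0.192), whereas the 19 autosomes together had 1.36 per Mb and ranged from 0.992 on chromosome 4 to 1.76 on chromosome 10. The X chromosome was thus 10.9-fold below the autosomes (multinomial Monte Carlo test by chromosome length, adjusted p = 0.0020, the smallest the draws gave, n = 3294 peaks). Chromosome 10 (225 peaks, 1.38 times the expectation, adjusted p = 0.0020, n = 3294 peaks in all) and chromosome 2 (275 peaks, 1.20 times, 0.0120) lay above the expectation. Chromosome 4 lay below it (152 peaks, 0.774 times, 0.0080). The test treats clustered peaks as independent. With neighbouring peaks counted once, chromosome 2 did not pass (1.16 times, adjusted p = 0.109, n = 3017 peaks). Without the 3 densest regions, a choice made after the data were seen, chromosome 10 did not pass (1.14 times, adjusted p = 0.186, n = 3223 peaks). Peaks on the X chromosome were narrower, with a median of 1023 bp against 1344 bp on the autosomes (permutation p = 0.0103). The expectation includes the X chromosome, which raises the ratio of every autosome.

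**Figure D4:**
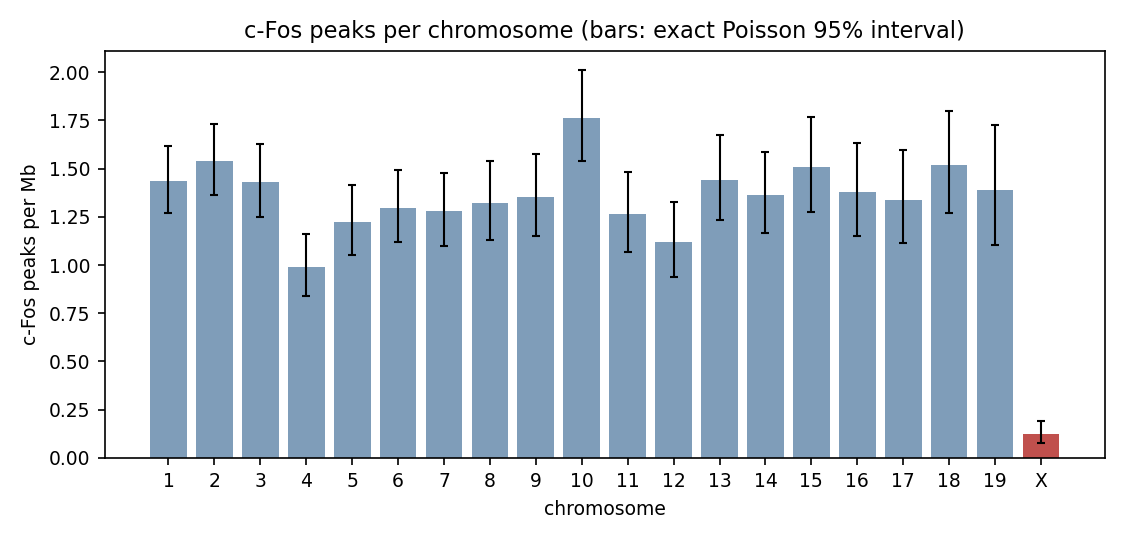
Number of c-Fos peaks per Mb (vertical axis) on each chromosome (horizontal axis), with exact Poisson 95% intervals as whiskers. The X chromosome, at 0.125 per Mb, lies below every autosome (0.992 to 1.76).

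The design also implies a comparison of c-Fos binding after kainic acid with that after PBS. It was not made, because peaks or read values of the PBS groups were not analysed here. The peaks above are therefore c-Fos peaks relative to IgG after kainic acid, and whether a given peak was absent after PBS was not tested.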

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

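No paired analysis was possible because the peak list has no values per replicate, so none could be left out either. Alternatives that need the genome sequence (motifs, repeats, peaks with an AP-1 match) were not run. Circular shifts, local placements for the distance and for the share inside genes, gene number as chromosome size, the gene body with 100 kb around it, and leaving out the X chromosome, wide peaks or dense regions were chosen after seeing the data. The shares at gene ends (1.60 to 3.10 times the placements over 8 alternatives) and inside genes (1.08 to 1.37, 3 alternatives), clustering (1.81 to 5.14, 5 alternatives), and the X chromosome (0.107 to 0.142 times the expectation, 2 alternatives) kept direction and call. So did the effectors (2.46 to 6.57, 10 alternatives). Activity-induced genes exceeded the pooled markers of other cell types in 8 alternatives (14.3 to 30.5 percentage points, Fisher's exact test, adjusted p 0.000144 to 0.0838). The difference did not pass with the gene body and 10 kb (14.3), and the cause was not tested. The comparison with pyramidal markers never passed (7.74 to 21.0 percentage points, adjusted p 0.0902 to 0.590). Of 85 named genes, 54 kept their nearest peak among the wider peaks.

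The wider peaks were 1647, by construction. The median distance to a gene end, 1.03 times the placements, became 0.895 with the wider peaks (p = 0.0719, n = 1647 peaks) and 0.978 with all gene types (p = 0.547), and 1.06 with local placements (p = 0.046); the cause was not tested. With gene number as chromosome size, 15 chromosomes passed instead of 4, since gene density differs. With neighbouring peaks counted once 3 passed (not chromosome 2), as without the 3 densest regions (not chromosome 10). Of the 16 lists, 2 passed in the main test, 4 with the gene body and 10 kb around it, 4 without matching and 1 with circular shifts, where the activity-induced transcription factors fell to 2.16 times the expectation (adjusted p = 0.0976, n = 24 genes); the cause was not tested. Interneuron markers passed in 4 of 10 alternatives (1.71 to 5.41 times the expectation, adjusted p 0.0064 to 0.262), glutamatergic synapse genes in 4 (1.57 to 2.91, 0.0016 to 0.811) and inhibitory synapse genes in 1. The other lists that crossed their expectation passed on neither side, and the cause was not tested. Astrocyte markers went from 0.979 to 1.27 with the wider peaks, 1.24 at 50 kb, 2.40 at 10 kb, 1.24 with the nearest gene only, 1.30 with the gene body and 10 kb, and 1.05 without matching. Vascular markers went from 1.04 to 0.880, 0.436, 0 of 16 genes (a ratio of 0), 0.900 and 0.602 under the first 5 of these. Inhibitory synapse genes fell to 0.894 at 50 kb and 0.721 at 10 kb. Ion channel genes rose to 1.73 with the nearest gene only, 1.85 with the gene body and 10 kb, 1.51 with the gene body and 100 kb, and 1.14 without matching. Housekeeping genes fell to 0.807 with the nearest gene only and 0.907 with the gene body and 10 kb. Dentate gyrus and CA3 markers rose to 1.07 with the nearest gene only, and genes of other organs to 1.22 with the wider peaks.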

Other observations

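Among 143 gene symbol families tested after the data were seen, olfactory receptor genes (Olfr, 50 of 1109 with a peak within 100 kb, 229 expected from circular shifts) and vomeronasal receptor genes (Vmn, 9 of 352, 70.8 expected) had fewer peaks (adjusted p = 0.0143 each, n = 1109 and n = 352 genes). These receptors belong to the olfactory system and lie in large gene clusters. No family had more peaks than expected after adjustment, and 6 families had an unadjusted p under 0.05. Genes with peaks inside them included Csmd1 (11 peaks), Enox1 (9), Msra (9), Anks1b (8) and Dlg2 (8); gene length was not taken into account.

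Of the tests below, those of gene density, of read depth and of glial and vascular markers (both distances) were chosen only after the result they bear on was seen. The list of developmental genes was drawn up after peaks at genes such as Dlx2 and Sim1 were seen, with its outcome still unknown.

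The X chromosome had 10.9-fold fewer peaks per Mb than the autosomes. Gene density and length argue little for this: autosomal genes matched on both gave 5.32 times as many genes with a peak as the 41 X genes found (218 expected, n = 963 genes, p = 0.0002, the smallest the draws can give). Lower read depth, for example with a single X chromosome per nucleus, stays open and may contribute. X peaks were narrower than autosomal peaks, as lower depth predicts. The median difference was −321 bp (1023 against 1344 bp, permutation p = 0.0103, n = 21 X peaks). Weaker signal from any other cause could also narrow peaks, so the width does not single out depth. Whether depth alone could lower the count this far was not tested, the sex of the mice was not used here, and filtering or mapping of X reads was not tested. No biological explanation was tested.

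Peaks lay near activity-induced genes more often than expected. The clustering of genes and peaks along chromosomes argues little for it: 0% of 10000 circular shifts gave as many as 33 of 63 such genes with a peak (mean 13.6, highest 26). This rests mainly on the effectors (0 shifts as high). For the transcription factors alone 60 of the 10000 shifts were as high (circular-shift Monte Carlo test, adjusted p = 0.0976 over the 16 lists, n = 24 genes). Their ratio to the expectation was 2.16 with shifts and 2.52 with matched lists. Clustering thus rarely gave the count of this list, but it was not excluded there at the adjusted threshold. A general property of genes used by pyramidal neurons cannot be told apart from inducibility, since pyramidal markers did not differ detectably (Fisher's exact p = 0.473) and were only 24 genes. Within 10 kb, the activity-induced transcription factors (5 of 24, 5.78 times the expectation) and the developmental ones (21 of 149, 3.89 times) both had more peaks than expected. For the transcription factor list, inducibility was therefore not told apart from signal at transcription factor genes. Why peaks lay near inducible genes thus stays open. A comparison with PBS, not made here, would show which peaks follow kainic acid, but not which of these gene properties they go with.

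Interneuron markers had peaks at short range (7 of 26 within 10 kb: Gad1, Gad2, Slc32a1, Sst, Dlx1, Dlx2 and Dlx6, where Dlx1 and Dlx2 adjoin), although nuclei were sorted for a CaMK2a-Cre tag. Nuclei of every other cell type passing the sort were tested at 100 kb first, without a decision (glial and vascular markers at 0.992 times their expectation, 15 of 70 against 11 of 26 interneuron markers, exact p = 0.0684). Repeated at 10 kb after the 10 kb counts were known, glial and vascular markers (3 of 70, 2.99 expected) lay below interneuron markers (exact p = 0.00355), but that distance was taken because the interneuron count was high there, so the repeat decides nothing and carry-over stays open. Signal at developmental transcription factor genes is a candidate explanation that the data met: 21 of 149 such genes outside the list, among them Tbx3, Pax3, Isl1 and Gata6, had a peak within 10 kb, 3.89 times the expectation (n = 149 genes, p = 0.0002, and 0.002 with circular shifts, each the smallest possible). It would cover only Dlx1, Dlx2 and Dlx6. Of interneuron markers that are not transcription factors, 4 of 18 had a peak within 10 kb, against 0.940 expected. That was 4.25 times the expectation (Monte Carlo test against matched lists, unadjusted p = 0.0226, n = 18 genes). These 4 genes, Gad1, Gad2, Slc32a1 and Sst, are among the 7 that made the count high at that distance. Their excess is therefore not separate support, and chance stays possible. They do not encode transcription factors, so signal at developmental transcription factor genes would not cover them. Interneuron nuclei in the sort may remain a source for these 4 genes, and that source was not tested separately.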
